A study of Mus musculus with 4 samples.

How the data were processed

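Gene expression was measured in the whole amygdala of male C57BL/6J mice aged 10 weeks, killed 6 h after an intraperitoneal injection of saline or of lipopolysaccharide (LPS, a bacterial cell wall component that activates Toll-like receptor 4). The mice were wild type or lacked the P2X7 receptor, an ATP-gated ion channel encoded by P2rx7, and each of the 4 groups held 4 mice per the labels. The labels give the LPS dose in 2 forms, 7.5 µg per mouse and 250 µg/kg. The files hold 4 arrays per group, 16 in all, each hybridised with Cy3-labelled cRNA made from total RNA. The labels do not tie single arrays to single mice, so the p-values measure the spread between arrays of a group. Over 9917 probes well above background on all arrays, the median absolute difference between any pair of arrays was at least 0.16 (log2), so no array was a copy of another.

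The per-array values are spot intensity on a linear scale, read with Agilent Feature Extraction 9.5 per the submitters' processing notes, and per the file headers the processed intensity had been background-subtracted and detrended within each array, with surrogate values for dim spots. No scaling between arrays had been applied to this column. The deposited processed list holds log2 values averaged by the authors over the 4 arrays of each group, for 24027 probes. Another deposited list holds the authors' linear fold change between group means for 4 comparisons and 9479 probes, with the direction in a separate column. In both, 32 per-array columns of detection calls were not used here.

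Each array held 42591 spots, of which 41174 were probes for transcripts, 1264 positive controls and 153 negative controls. Control spots were left out, spots marked by the scanner software as outliers (0 to 79 per array) were set to missing, and no spot was saturated. Probes were named through their RefSeq accession where the reference table held it (24844 probes), and 16330 probes kept the name in the file, giving 28632 names. Coordinates are those of the files, on mouse build mm9. The 75th percentile of the processed intensity ranged from 345.9 to 1164.7 between arrays, and 58.1% to 71.9% of probes lay well above background. The number of arrays limits the precision.

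Values were log2 of the processed intensity minus the 75th percentile of that array. A probe was kept where it lay well above background on at least 3 of the 4 arrays of at least 1 group (28347 probes). Each gene was represented by the kept probe with the highest mean over all arrays, which left 19463 genes, 13941 of them with a gene symbol. limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table version 1.17.8, statmod 1.5.0) was fitted to a model of 4 group means over all 16 arrays, so that every comparison shared 1 estimate of the spread. The comparisons were LPS against saline within each genotype, knockout against wild type within each treatment, and the interaction, that is the LPS response in knockout minus that in wild type. P-values were adjusted by the Benjamini-Hochberg method over genes, and genes with an adjusted p under 0.05 were called. Changes are log2 differences ± the standard error of the model, with n = 4 arrays per group, and levels are log2 relative to the 75th percentile of the array, ± SD. The model pools the spread of all groups, so a group whose arrays disagree widens the error of a gene in comparisons among the other groups. In comparisons that hold that group, the pooled error can be smaller than the group's own spread would give. The p-values there can then be too small.

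Where the probe of a gene was not well above background on any array of a group, only a bound is given, written as "at least N-fold". The bound sets the mean of the bright group against the mean, over the arrays of the dim group, of the lowest signal among probes well above background or the probe's own signal, whichever was higher. List medians were also computed with such genes at their bound.

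In each list of genes, members called over all genes were counted, then members called when p was adjusted over the list alone. The 40 lists hold response pathways, markers of cell types and of neighbouring brain regions, transmitter systems and protein complexes. Some genes are in several lists. Lcn2, Serpina3n, Steap4 and Cp are in both the acute-phase and the reactive astrocyte list. Cxcl10 is in the cytokine, interferon and reactive astrocyte lists. Results of such lists are not independent. Each list was tested against the other genes with camera (preset correlation 0.01), with Benjamini-Hochberg adjustment over lists within a comparison, and again with an estimated correlation. The mean level of each list per array was compared by a 2-sided exact permutation test, whose smallest possible p for 4 against 4 arrays is 0.0286. With 4 against 4 arrays, chance leaves the groups of 2.86% of genes without overlap. Genes within 10 Mb of P2rx7 were compared with other genes by a 2-sided Fisher's exact test.

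The named genes were, for each comparison, the 10 highest and 10 lowest changes among called genes whose groups did not overlap (the overlap rule was dropped for the interaction) and that had a symbol other than a clone name, predicted gene or accession. Where none passed, the 5 with the smallest p were taken. P2rx7 was given throughout, and up to 4 members of each list with the smallest p could be named. Which of these list members are printed was chosen after their values were seen. The single-gene results of 3 genes that the rule allowed are not reported here. The groups, tests, lists, naming rule and most other settings tried were fixed before the data were examined.

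The arrays lay on 4 slides read in 2 scan sessions. Slides 1 and 2 held wild-type arrays (session 1) and slides 3 and 4 knockout arrays (session 2), with 2 saline and 2 LPS arrays on each slide. Genotype and scan session therefore cannot be told apart. Slide was tried as a fixed block for LPS, as a random block in all comparisons (correlation within a slide 0.202), and each slide alone. Further alternatives were normexp background correction (offset 50), quantile normalization, median centring, other filters and probe choices, a variance trend, a 2-fold minimum, and fits without each array or slide. Fits without wild-type saline replicates 1 and 2, with a correction for the base composition of the probes, and with calls that needed at least 2 probes per gene were added after the data were seen.

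The code was tested on simulated arrays of 19463 genes with 200 genes changed. The noise was normal and independent between genes, with 1 SD per gene in all groups and no effect of slide or scan session. The shares recovered therefore do not apply to genes whose arrays disagree within a group. For LPS in wild type, 50.7% of genes changed by 1 on the log2 scale were recovered, 86.6% at 2 and 98.5% at 4. For LPS in knockout these shares were 47.8%, 91.0% and 97.0%, for genotype after saline 40.3%, 91.0% and 98.5%, for genotype after LPS 34.3%, 92.5% and 100.0%, and for the interaction 11.9%, 71.6% and 97.0%. No gene was recovered in the wrong direction, and 13, 10, 4, 14 and 7 unchanged genes were called in the same order of comparisons.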

Results

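The design crossed genotype (wild type or P2X7 receptor knockout) with treatment (saline or LPS) and asked how loss of the receptor alters gene expression in the amygdala, with and without an immune challenge. Each of the 4 groups had 4 arrays. The array 75th percentile of intensity ranged from 581.3 to 1164.7 in wild type and from 345.9 to 614.0 in knockout, and 58.1% to 71.9% of probes lay well above background. The first principal component held 55.9% of the variance and separated the genotypes, which were also scanned in separate sessions.

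P2rx7, the targeted gene, was measured by 2 probes. The probe with the higher signal, at chromosome 5, 123134194 to 123134253 (mm9), was lower in knockout, by −1.51 ± 0.25 (log2, SE, n = 4 per group, adjusted p = 0.000207) after saline and by −1.65 ± 0.25 (adjusted p = 0.000105) after LPS. Its level was 0.42 ± 0.51 (SD, n = 4) in wild-type saline, 0.30 ± 0.28 in wild-type LPS, −1.09 ± 0.34 in knockout saline and −1.36 ± 0.27 in knockout LPS. The 8 knockout arrays lay between −1.69 and −0.80 and the 8 wild-type arrays between −0.15 and 0.90. The other probe, within 123120528 to 123123413, did not differ between genotypes (0.24 ± 0.29, adjusted p = 0.51, and 0.06 ± 0.29, adjusted p = 0.875). Whether either probe lies in the deleted part is unknown here, so the lower signal separates the genotypes but does not by itself check the labels. The genotypes were scanned in separate sessions, and their groups did not overlap for 46.14% of all genes after saline and 51.88% after LPS. Separation of the genotypes alone thus does not set P2rx7 apart from other genes. With the probes' base composition corrected, an alternative added after the data were seen, the difference was −0.81 after saline and −1.0 after LPS, and both calls were kept. P2rx7 did not change with LPS (−0.12 in wild type, adjusted p = 0.992, and −0.26 in knockout, adjusted p = 0.665). The authors' deposited table lists P2rx7 as 2.85-fold down after saline and 3.14-fold down after LPS.

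**Figure D1:**
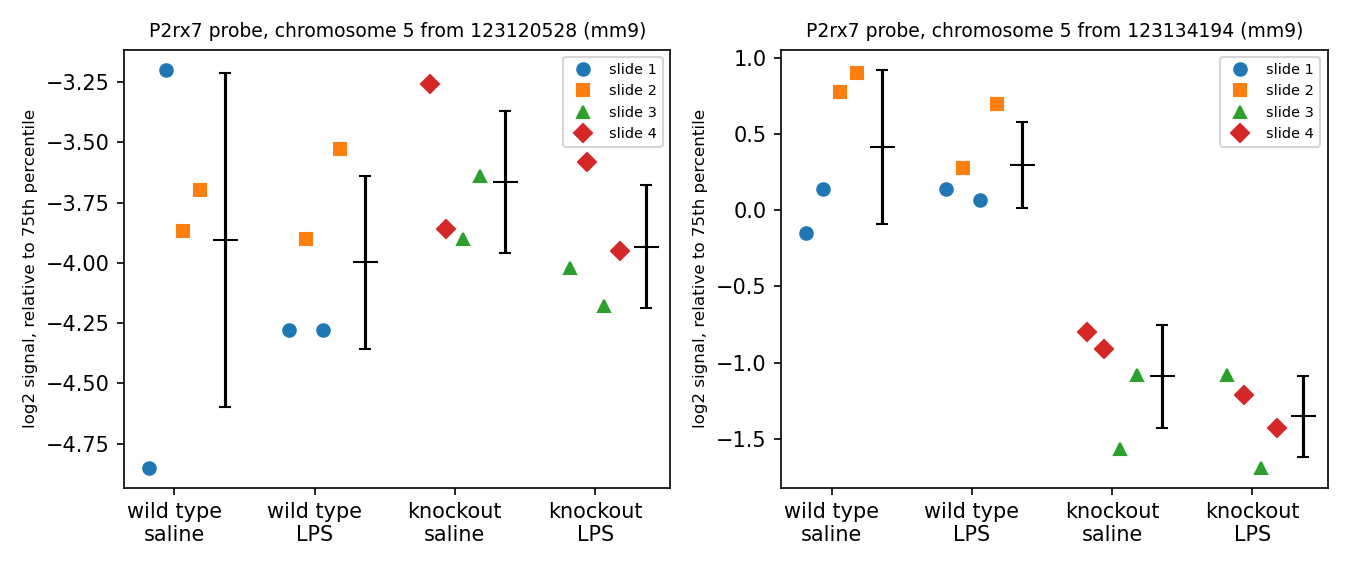
Level of the 2 P2rx7 probes (log2 relative to the array 75th percentile) on each array of the 4 groups, with the group mean ± SD. For the probe with the higher signal the 8 knockout arrays lie between −1.69 and −0.80, below the 8 wild-type arrays, and for the other probe the genotypes overlap.

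In the amygdala of knockout mice, 18 of 20 cytokines and chemokines, 31 of 36 interferon-stimulated genes and 11 of 15 acute-phase genes rose 6 h after LPS (for each list adjusted p = 0.0687 with an estimated correlation). Cxcl10, an interferon-inducible chemokine, rose by 9.87 ± 1.5 (log2, SE, n = 4 per group, adjusted p = 0.00225) and the monocyte attractant Ccl2 by 8.74 ± 1.44 (adjusted p = 0.00318). Ccl5 rose by 7.15 ± 1.32 and the myeloid receptor Cd300lf by 6.87 ± 0.97. The acute-phase gene Saa3 rose at least 199-fold, Gbp6 at least 48.1-fold and the neutrophil attractant Cxcl1 at least 39.9-fold. The metalloprotease Mmp3 rose at least 26.6-fold and Csf3, which encodes a granulocyte growth factor, at least 25.6-fold. The pentraxin Ptx3 rose at least 43.5-fold, although the probe that passed on all 16 arrays did not differ (−0.28, adjusted p = 0.624). The falls were smaller and included the amino acid transporter Slc38a5 (−3.72 ± 0.74, adjusted p = 0.00907), Dapl1 (−3.36 ± 0.56), the lectin Cd209f (−3.00 ± 0.45) and the iron exporter Slc40a1 (−2.96 ± 0.48). Degs2 (−2.94 ± 0.48), Susd3 (−2.87 ± 0.60) and Gkn3 (−2.75 ± 0.40) fell too. The microglial receptor Gpr34 fell at least 4.68-fold, Slc16a4 at least 3.95-fold and Tnfrsf17 at least 3.37-fold. Cxcl10, Cd300lf and Ifi44 lay well above background on 1 of the 4 knockout saline arrays, Plac8 on 2, and Dapl1, Cd209f, Abcb1a and Tek on 1 of the 4 knockout LPS arrays. In all, 708 of 19463 genes were called, 486 up and 222 down, and 597 of them changed at least 2-fold. The groups of 2196 genes (11.28%, against 2.86% by chance) did not overlap. In the authors' deposited table, 817 probes were listed as up and 303 as down at least 2-fold.

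Of 36 interferon-stimulated genes, 31 rose and 5 did not pass (35 rose when adjusted over the list alone), with a median of 3.46 (3.27 with dim genes at their bound). Examples were Ifi44 (4.58 ± 0.60), Gbp3 (4.26), Oasl2 (3.84) and Mx2 (3.14 ± 0.40). Of 20 cytokines and chemokines, 18 rose (20 when adjusted over the list alone), with a median of 4.76 (3.65 with bounds). Ccl4, which attracts leukocytes, rose by 4.93 ± 0.54 (adjusted p = 0.0004), Cxcl16 by 2.53, Ccl3 at least 21.0-fold and the interleukin-1 antagonist Il1rn at least 11.8-fold. NF-kB targets rose in 15 of 22 cases (19 when adjusted over the list alone; median 1.96, 1.83 with bounds), among them Tlr2 (4.36 ± 0.65), the adhesion molecule Icam1 (3.56) and Birc3 (2.55). Acute-phase genes rose in 11 of 15 cases (15 over the list alone; median 3.76, 3.32 with bounds), with Saa1 (3.76) and Serpina3n (3.32 ± 0.62). Lbp, which carries LPS to its receptor, rose by 1.98, a call that normexp ended at 0.22. Reactive astrocyte markers rose in 8 of 13 cases (10 over the list alone; median 3.11, 2.82 with bounds), with Timp1 (4.28), Osmr (3.77) and Gfap (1.13), and genes of activated endothelium in 7 of 12 (8 over the list alone; median 2.79), with Socs3 (3.73) and Cebpd (3.60). Members are shared between these lists, among them Cxcl10 and Serpina3n, so a rise in 1 list is not independent of the others. The adjusted p = 0.0687 with an estimated correlation for each of these 6 lists, whose camera calls were thus lost, and their medians stayed above 0 under normexp, quantile and median scaling.

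Glucocorticoid-responsive genes rose in 8 of 18 cases (15 when adjusted over the list alone; median 1.0; adjusted p = 0.0687 with an estimated correlation), with Fkbp5 (1.91), Nfkbia (1.64) and the metallothionein Mt2 (1.29 ± 0.24). Complement and antigen presentation genes rose in 10 of 20 cases (13 up and 2 down over the list alone; median 1.17; adjusted p = 0.155 with an estimated correlation), with the class I genes H2-D1 (1.44) and H2-T23 (1.41). In the inflammasome and interleukin-1 list, 5 of 14 rose (7 over the list alone; median 0.78; adjusted p = 0.0687 with an estimated correlation), including Casp4 (3.69), which senses intracellular LPS, and Il1b (2.94 ± 0.63, adjusted p = 0.0136). In the LPS receptor pathway 7 of 17 rose (8 over the list alone), with the co-receptor Cd14 at 3.72. Its median of 0.68 turned to −0.02 under normexp, and adjusted p = 0.0687 with an estimated correlation. Of 8 measured neutrophil and monocyte markers, Plac8 (3.74) rose (6 over the list alone; median 2.36, 2.05 with bounds; adjusted p = 0.14 with an estimated correlation). Among purinergic genes 5 of 23 rose, including P2ry2 (2.82), the AMP-degrading enzyme Nt5e (1.62) and the adenosine receptor Adora2b (1.18), and Entpd1, which degrades ATP, fell by 1.11. The list did not pass (camera adjusted p = 0.0704, but 0.0311 without knockout saline replicate 1 and 0.0487 without knockout LPS replicate 3). Microglia markers had a median of −0.52 (camera adjusted p = 0.000232, adjusted p = 0.14 with an estimated correlation). Gpr34 and Olfml3 (−1.49) fell, and over the list alone 8 fell and 1 rose. Gpr17, a marker of oligodendrocyte precursors, fell by 1.61 (1 of 9 in its list, 4 over the list alone; adjusted p = 0.0877 with an estimated correlation). The preset camera call of that list was lost without knockout saline replicate 2 or 4 or knockout LPS replicate 3 (camera adjusted p = 0.0517 to 0.0651). Among endothelial and barrier markers the drug efflux pump Abcb1a (−2.40), the angiopoietin receptor Tek (−2.43) and Itm2a (−1.42) fell and 11 of 14 did not pass (5 down and 3 up over the list alone), and the list did not pass (camera adjusted p = 0.365). No ribosomal protein gene was called (0 of 78 with limma, also over the list alone); their median of −0.24 passed camera (adjusted p = 0.000508, adjusted p = 0.581 with an estimated correlation), was −0.14 without knockout saline replicate 1 (camera adjusted p = 0.0698) and turned to 0.06 under normexp. No member of the GABA, glutamate, monoamine or neuropeptide lists was called with limma, over all genes or over the list alone.

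With slide as a block, 939 genes were called for LPS in knockout. Within slide 3 alone 882 were called and within slide 4 alone 178. The median of interferon-stimulated genes was 3.35 within each slide, that of cytokines 4.95 and 4.66, that of NF-kB targets 1.83 and 2.09 and that of microglia markers −0.47 and −0.64. Cxcl10 rose by 9.70 ± 0.20 within slide 3 (adjusted p = 0.00118) and 10.05 ± 0.58 within slide 4 (adjusted p = 0.00148). Leaving out slide 3 or slide 4 left 1 and 0 calls with limma (2193 genes at an unadjusted p under 0.05 without slide 4). The fit without slide 4 holds the same knockout arrays as slide 3 alone, but pools the spread of the wild-type arrays into its error. Leaving out knockout LPS replicate 1, 2 or 3 left 452, 430 and 439. Normexp called 429, of which 44.3% rose against 68.6% here, and moved the median change of all genes from −0.09 to −0.22.

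**Figure D2:**
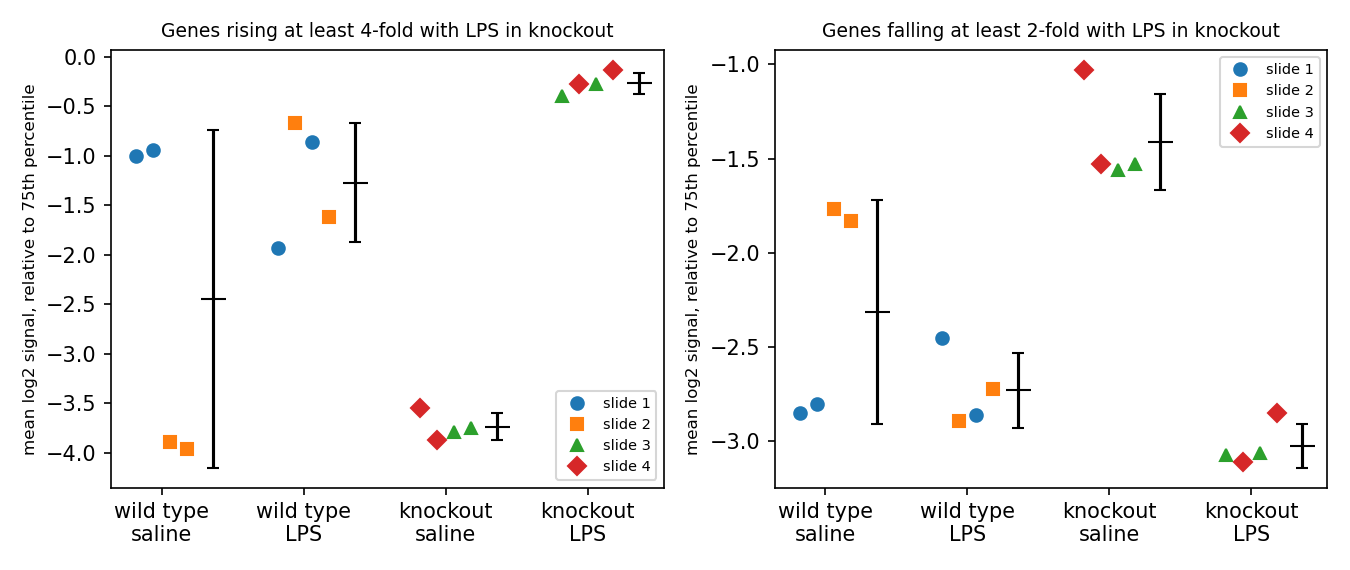
Mean level per array (log2 relative to the array 75th percentile) of the 241 genes that rose at least 4-fold and the 155 genes that fell at least 2-fold with LPS in knockout, with group means ± SD; points are arrays and markers give the slide. Wild-type saline replicates 1 and 2 (−1.0 and −0.94 for rising genes) lie near the LPS arrays, and wild-type saline replicates 3 and 4 (−3.89 and −3.96) near the knockout saline arrays.

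In wild-type mice, the genes that rose with LPS in knockout stood high on the 4 LPS arrays and also on 2 of the 4 saline arrays. On a scale where 0 is the mean of knockout saline and 1 that of knockout LPS, the 241 rising genes lay at 0.52, 0.88, 0.83 and 0.61 on wild-type LPS arrays, at 0.79 and 0.81 on saline replicates 1 and 2, and at −0.04 and −0.06 on saline replicates 3 and 4. Tissue markers differed between the same arrays, with hippocampus markers at −1.09 and −0.88 on saline replicates 1 and 2 and 0.22 and 0.27 on replicates 3 and 4, and oligodendrocyte markers at 0.63 and 0.58 against 1.75 and 1.79. Cxcl10 was thus −1.06 ± 4.49 (SD, n = 4) after saline and 2.25 ± 1.54 after LPS, a difference of 3.31 ± 1.5 (SE, adjusted p = 0.734). The interferon-inducible genes Cxcl9 (3.23 ± 1.23, adjusted p = 0.662), Isg15 (1.90 ± 0.69, adjusted p = 0.643) and Mx1 (2.11 ± 0.69, adjusted p = 0.599) did not pass either. With limma, 2 genes were called, the transcripts AK053596 (0.93) and ENSMUST00000069631 (−1.63), each at adjusted p = 0.0437, and 1285 genes had an unadjusted p under 0.05. The groups of 933 genes (4.79%, against 2.86% by chance) did not overlap. The genes with a symbol and the smallest p were Ccl21a, a lymphoid chemokine (−5.68 ± 0.93, adjusted p = 0.0842), Cep68 (at least 1.51-fold, adjusted p = 0.152), Cdc7 (0.78 ± 0.15, adjusted p = 0.184), Serp2 (−1.76, adjusted p = 0.184) and Ifi35 (1.65, adjusted p = 0.199). The authors' deposited table lists 340 probes as up and 304 as down at least 2-fold.

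No list had a member called for LPS in wild type with limma. The median change was 1.25 for interferon-stimulated genes (camera adjusted p = 1.24e-21, adjusted p = 0.385 with an estimated correlation) and 1.12 for cytokines and chemokines (1.27e-06, adjusted p = 0.432 with an estimated correlation). It was 1.27 for acute-phase genes (4.2e-10, adjusted p = 0.385 with an estimated correlation). It was 0.42 for glucocorticoid-responsive genes (2.03e-08, adjusted p = 0.26 with an estimated correlation) and −0.45 for microglia markers (5.72e-05, adjusted p = 0.282 with an estimated correlation). When p was adjusted over the list alone, none of the interferon-stimulated, cytokine or acute-phase genes passed, and 1 glucocorticoid-responsive gene and 1 microglia marker did. Within slide 1 the medians were −0.22 for interferon-stimulated genes, −0.66 for cytokines, −0.46 for acute-phase genes and −0.56 for NF-kB targets. Within slide 2 they were 2.74, 3.06, 3.24 and 1.70. Cxcl10 changed by −0.61 within slide 1 (adjusted p = 0.891) and by 7.23 within slide 2 (adjusted p = 0.0513), and 2 genes were called within slide 1, 245 within slide 2 and 3 with slide as a block. Without saline replicates 1 and 2, an alternative added after the data were seen, 611 genes were called, 372 up and 239 down. Then 31 of 36 interferon-stimulated genes (median 2.63), 10 of 20 cytokines (3.09) and 14 of 15 acute-phase genes (2.95) rose, Cxcl10 by 7.19 ± 0.71 and Cxcl9 by 6.59 ± 0.36. That comparison leaves 2 saline arrays, both on slide 2. Without each array in turn the count was 5 (wild-type saline replicate 1), 6 (wild-type LPS replicate 2), 3 (wild-type LPS replicate 4 or knockout LPS replicate 4), 19 (knockout saline replicate 1), 4 (knockout saline replicate 2) and 0 without any of the other 10 arrays, with 828 to 1726 genes at an unadjusted p under 0.05.

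**Figure D3:**
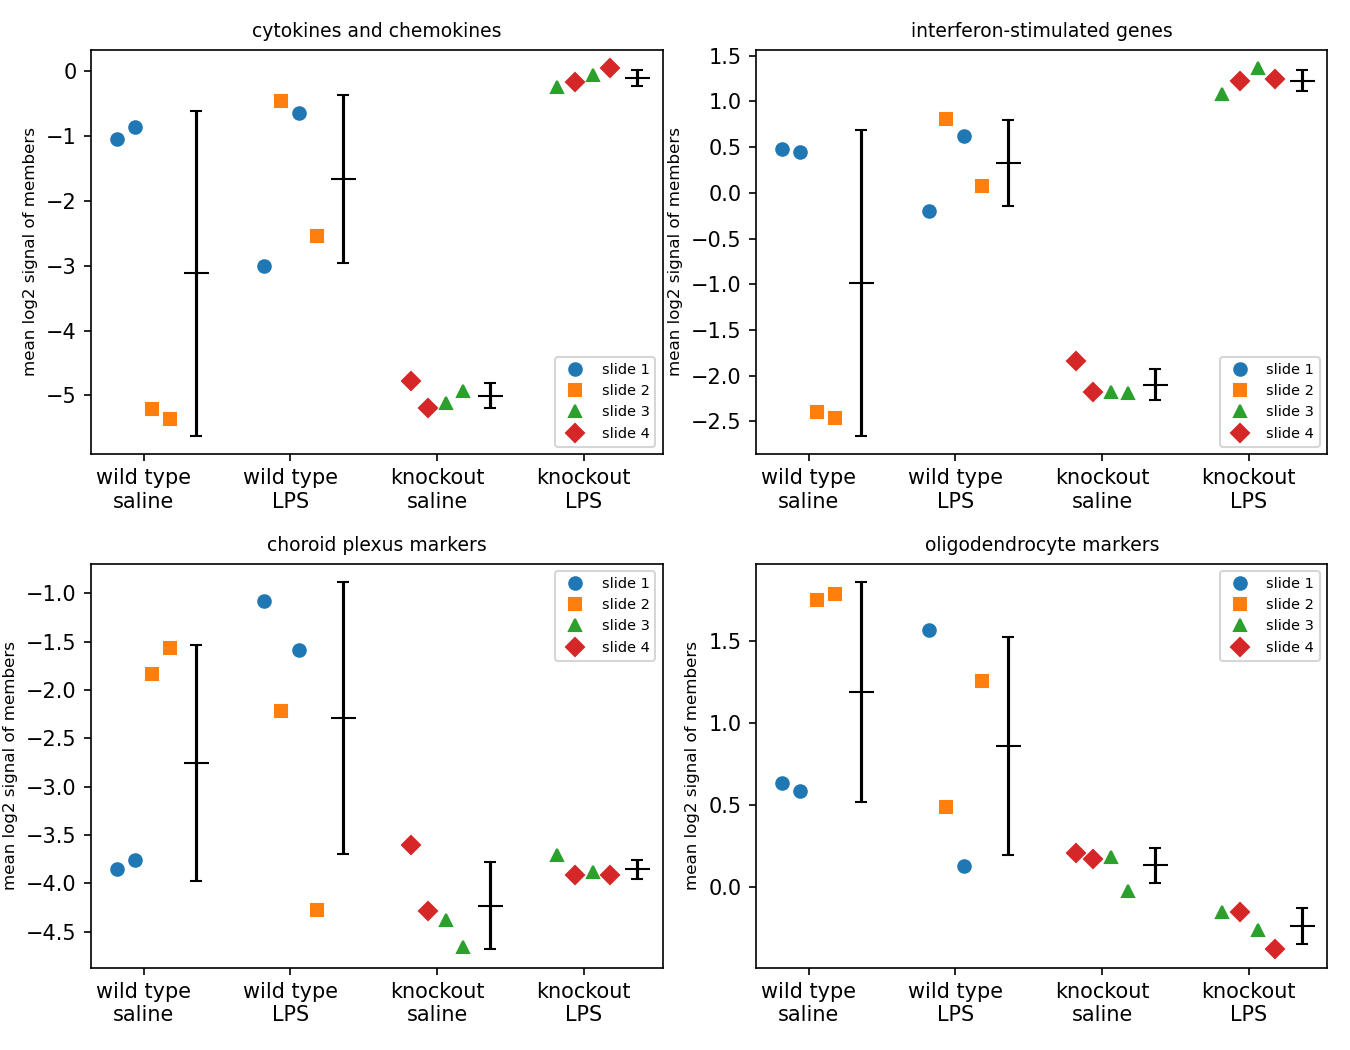
Mean level per array (log2 relative to the array 75th percentile) of cytokines and chemokines, interferon-stimulated genes, choroid plexus markers and oligodendrocyte markers in the 4 groups, with group means ± SD; points are arrays and markers give the slide. Interferon-stimulated genes lie at 0.48 and 0.45 on wild-type saline replicates 1 and 2 and at −2.40 and −2.46 on replicates 3 and 4.

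After saline, 65 of 78 ribosomal protein genes and 63 of 86 genes of oxidative phosphorylation were higher in knockout than in wild type, and 8 of 13 oligodendrocyte markers and 9 of 13 striatum markers were lower. For each of these lists adjusted p = 0.704 with an estimated correlation. Cox7c, a subunit of cytochrome c oxidase, was higher by 3.47 ± 0.21 (log2, SE, n = 4 per group, adjusted p = 2.68e-08), Cox6c by 2.12 and the ribosomal protein gene Rpl30 by 2.72 ± 0.22 (adjusted p = 3.26e-07). The myelin gene Mal was lower by 2.00 ± 0.31 (adjusted p = 0.000112), and the dopamine receptor Drd2 (−2.31) and the transcription factor Isl1 (−2.52), both of striatal neurons, were lower too, although normexp ended the call of Drd2 (−0.79) and turned Isl1 to 0.06. Among the largest differences, the muscarinic receptor Chrm1 (5.17 ± 0.51), Ugt2b34 (5.0 ± 0.43), Trim55 (4.88 ± 1.1), Hspa4 (4.74 ± 1.25) and Mydgf (4.67 ± 0.57) were higher in knockout, Krtap4-13 at least 13.7-fold and Tex101 at least 8.17-fold. Nrxn3 (5.23 ± 0.82), Hspa8 (4.90 ± 0.71) and Mb21d2 (4.72 ± 0.56) were also higher by their brightest probe, but another probe of each was called in the opposite direction. Nrxn3, Chrm1 and Mb21d2 lay well above background on 2 of the 4 wild-type saline arrays. Pon2 (−3.68 ± 0.49), Serpina3n (−3.52 ± 0.62), Gprin3 (−3.33 ± 0.38, 0.10 under normexp) and Hdac2 (−3.31 ± 0.66) were lower. Serpina3n is an acute-phase gene, and the level of that list was 0.05 and 0.06 on wild-type saline replicates 1 and 2 against −4.39 and −4.36 on replicates 3 and 4. Without replicates 1 and 2, an alternative added after the data were seen, Serpina3n differed by −2.16 ± 0.49 (adjusted p = 0.00464), Nrxn3 by 3.44, Hspa8 by 3.12 and Hspa4 by 2.73 (adjusted p = 0.112), and the call of Ptx3 was lost (adjusted p = 0.118). Ptx3 was at least 8.24-fold lower, Supt7l at least 4.21-fold and Fam83d at least 2.63-fold. Normexp turned Supt7l to 0.08 and Fam83d to 0.88, and the Ptx3 probe that passed on all 16 arrays differed by 0.40 (adjusted p = 0.198). In all, 9907 genes (50.9%) were called, 5559 up and 4348 down, 5774 of them at least 2-fold, and the groups of 8980 genes (46.14%, against 2.86% by chance) did not overlap. The authors' deposited table lists 3627 probes as up and 3958 as down at least 2-fold.

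Of 78 ribosomal protein genes, 65 were higher and 3 lower (the same numbers when adjusted over the list alone), with a median of 1.25 (camera adjusted p = 1.93e-14, adjusted p = 0.704 with an estimated correlation). Of 86 oxidative phosphorylation genes, 63 were higher and 1 lower (68 and 1 over the list alone; median 0.98; adjusted p = 0.704 with an estimated correlation). Both medians stayed above 0 under normexp (0.83 and 0.70), where the median of all genes moved from 0.07 to 0.43, and under quantile scaling (0.71 and 0.62). Oligodendrocyte markers were lower in 8 of 13 cases (9 over the list alone; median −1.39), among them Mog (−1.76, a call lost under normexp), and striatum markers in 9 of 13 (10 over the list alone; median −1.14); for both, adjusted p = 0.704 with an estimated correlation. Circadian clock genes were lower in 8 of 16 cases and higher in 1 (the same over the list alone; median −0.56, but 0.04 under normexp; adjusted p = 0.704 with an estimated correlation), with Nr1d2 (−1.80), Per3 (−2.02) and Npas2 (−1.75), the last 2 of which reversed under normexp (0.27 and 0.21). Choroid plexus markers were lower in 4 of 12 cases (4 over the list alone; median −1.22, −1.0 with bounds, but 0.33 under normexp; adjusted p = 0.704 with an estimated correlation), and their camera call was lost without wild-type saline replicate 3 or 4 or knockout saline replicate 2, 3 or 4 (camera adjusted p = 0.0675 to 0.118). Their level ranged over the wild-type arrays, with Ttr, the main secreted protein of the choroid plexus, between −6.34 and −0.02. The purinergic receptor P2rx2 was higher (1.80) and P2ry1 lower (−1.96, but −0.53 and not called under normexp), and their list did not pass (6 up and 8 down of 23, 7 and 9 over the list alone; camera adjusted p = 0.402). Aif1, a microglial gene, was higher (2.47), as 5 of 16 microglia markers were, and that list did not pass (camera adjusted p = 0.364). Glo1, whose copy number varies between mouse strains, was higher by 2.32. Its list of strain markers did not pass without knockout saline replicate 1, a list test added after the data were seen. There 2 of 8 members were higher and 2 lower (median 0.22, camera adjusted p = 0.643).

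Some interferon-stimulated genes, cytokines and genes of activated endothelium were lower in knockout saline than in wild-type saline, where genes that respond to LPS stood high on replicates 1 and 2. For each of these 3 lists adjusted p = 0.704 with an estimated correlation, and the camera call was lost without wild-type saline replicate 1 or 2 alone (camera adjusted p = 0.0565 to 0.118). Of 36 interferon-stimulated genes 13 were lower and 2 higher (the same over the list alone, median −1.09). Of 20 cytokines and chemokines 8 were lower (8 over the list alone, median −1.63, −0.77 with bounds, but 0.41 under normexp). Of 12 genes of activated endothelium 6 were lower (7 over the list alone, median −1.77), including Vcam1 (−1.91). The other inflammatory lists did not pass, although with the preset correlation NF-kB targets, acute-phase genes, the LPS receptor pathway and reactive astrocyte markers did without wild-type saline replicate 3 or 4 (camera adjusted p = 0.00317 to 0.0217). With all arrays and an estimated correlation none of these lists passed. Of 22 NF-kB targets 8 were lower and 1 higher (camera adjusted p = 0.164), and of 15 acute-phase genes 4 were lower (2 over the list alone, camera adjusted p = 0.0611). In the LPS receptor pathway 10 of 17 were lower and 1 higher (camera adjusted p = 0.0611), and of 13 reactive astrocyte markers 5 were lower (camera adjusted p = 0.0713). Of 20 complement and antigen presentation genes 4 were higher and 5 lower (camera adjusted p = 0.691), and of 14 inflammasome genes 3 were higher and 1 lower (3 and 0 over the list alone, camera adjusted p = 0.911). Where no other number is given, the counts over the list alone were the same. Cxcl10 was lower by 4.57 ± 1.5 (adjusted p = 0.0189) and Ccl2 by 3.97 ± 1.44 (adjusted p = 0.0316, 0.0503 with slide as a random block), Gbp4 at least 6.54-fold and Il6 at least 2.79-fold, while normexp turned Gbp4 to 0.02 and Il6 to 0.72 and ended the calls of Cxcl10 (adjusted p = 0.203) and Ccl2 (adjusted p = 0.296). Without wild-type saline replicates 1 and 2, the medians of interferon-stimulated genes, cytokines and activated endothelium were 0.23, 0.24 and −0.34, 6 interferon-stimulated genes were higher and none lower, Cxcl10 differed by −0.69 (adjusted p = 0.466) and Ccl2 by −0.41 (adjusted p = 0.743), and Il6 did not pass (adjusted p = 0.311). The oligodendrocyte (−1.72, 10 lower), striatum (−1.54, 9 lower) and ribosomal (1.06, 59 higher and 1 lower) differences were still called there. With all arrays and an estimated correlation, each of these lists had adjusted p = 0.704 with camera.

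The genotype calls differed between probes of the same gene. Of 2385 genes with at least 2 probes called after saline, 923 (38.7%, 95% exact binomial interval 36.7% to 40.7%) had probes called in opposite directions, and after LPS 857 of 2111 (40.6%, 38.5% to 42.7%). For LPS in knockout this was 0 of 92 genes, which allows up to 3.9%. Across 4421 genes with 2 probes, which are not independent replicates, the correlation between the probes' changes was 0.222 for genotype after saline, 0.175 after LPS and 0.657 for LPS in knockout. With calls that needed at least 2 probes in 1 direction, 1462 genes were called after saline, 576 up and 886 down, and 1254 after LPS, 467 up and 787 down, so that most were lower. Normexp placed 72.8% of the calls after saline higher in knockout and no filter on dim probes 66.3%, against 56.1% here. Normexp moved the median of all genes from 0.05 to 0.15 after LPS, and no filter moved it to 0.32 after saline and 0.23 after LPS. With slide as a random block, 8570 genes were called after saline, 8569 of them shared, and 7848 after LPS, 7846 shared. Genotype and scan session cannot be told apart.

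After LPS, ribosomal protein genes and genes of the respiratory chain were again higher in knockout in most cases and oligodendrocyte markers lower, although for each of these 3 lists adjusted p = 0.922 with an estimated correlation. Cox7c was higher in knockout by 3.30 ± 0.21 (log2, SE, n = 4 per group, adjusted p = 3.83e-08), Cox6c by 2.03, Rpl30 by 2.72 ± 0.22 and Rpl19 by 2.06. Mal was lower by 1.91 ± 0.31, Mobp by 1.76, Gpr17 by 1.58 and Fa2h, which makes the hydroxylated lipids of myelin, by 3.15 ± 0.37. Ribosomal protein genes were higher in 61 of 78 cases and lower in 3 (62 and 3 when adjusted over the list alone; median 1.03; camera adjusted p = 1.45e-12). Oxidative phosphorylation genes were higher in 55 of 86 cases and lower in 3 (56 and 3 over the list alone, median 0.76). Oligodendrocyte markers were lower in 10 of 13 and higher in 1 (the same over the list alone; median −1.45; camera adjusted p = 0.00428). The medians of these lists kept their sign under normexp, quantile and median scaling. Striatum markers were lower in 5 of 13 cases (4 over the list alone; median −0.64) and did not pass (camera adjusted p = 0.108). The chemokines Ccl3 (4.01 ± 0.62, adjusted p = 0.000112; well above background on 2 of the 4 wild-type LPS arrays) and Ccl4 (3.18 ± 0.54, adjusted p = 0.000256), the inflammasome sensor Nlrp3 (2.17) and Nfkbie (2.14) were higher in knockout. NF-kB targets were higher in 8 of 22 cases (8 over the list alone) and cytokines in 6 of 20 (4 over the list alone). Interferon-stimulated genes were higher in 7 of 36 (4 over the list alone) and inflammasome genes in 7 of 14 (7 over the list alone), and none of these 4 lists passed (camera adjusted p = 0.108 each). Without wild-type LPS replicate 3, NF-kB targets (0.0314), cytokines and interferon-stimulated genes (0.0493 each) had a camera adjusted p past the threshold.

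Among the largest differences after LPS, Nrxn3 (6.79 ± 0.82, another probe opposite), Hspa4 (6.41 ± 1.25), C1ra of the complement system (5.26 ± 0.88), Ugt2b34 (5.08 ± 0.43), Chrm1 (5.07 ± 0.51), Ccl21a (4.72 ± 0.93) and Zfp112 (4.66 ± 0.41) were higher in knockout, Vmn1r46 at least 25-fold, Tex101 at least 9.65-fold and Zc3h12a at least 8.32-fold. The probe of Chrm1 that passed on all 16 arrays did not differ (0.28, adjusted p = 0.291). Nrxn3, Chrm1, C1ra, Ccl21a and Zfp112 lay well above background on 1 of the 4 wild-type LPS arrays and Hspa4 on 2, Duox2 on 2 of the 4 knockout LPS arrays and Jrkl on 1. Duox2 (−3.82 ± 0.83), Jrkl (−3.72 ± 0.41) and Prm1 (−3.23 ± 0.19) were lower, Dnajb8 at least 8.25-fold and Kif12 at least 6.10-fold. Syt6 was at least 4.02-fold lower, Supt7l at least 3.73-fold and Otx2 at least 2.29-fold, and Syt6 had adjusted p = 0.0629 with slide as a random block. Otx2 is a choroid plexus marker and ranged with that list over the wild-type LPS arrays, at −3.11, −4.44, −1.29 and −6.23 on replicates 1 to 4, where the list level was −1.08, −2.22, −1.59 and −4.28. Normexp ended its call (−0.30, adjusted p = 0.613) and those of Jrkl, Kif12, Per3, Supt7l and Syt6 (adjusted p = 0.0522 to 0.379), and the choroid plexus list did not pass (5 of 12 lower, also over the list alone; camera adjusted p = 0.0824, but 0.00155 without wild-type LPS replicate 4). Per3 (−1.99), Nr1d2 (−1.69) and P2ry1 (−2.13) were lower and P2rx2 (2.24) and Glo1 (2.19) higher, as after saline. In all, 9178 genes (47.2%) were called, 5043 up and 4135 down, 5199 of them at least 2-fold, and the groups of 10097 genes (51.88%, against 2.86% by chance) did not overlap. The authors' deposited table lists 3394 probes as up and 3350 as down at least 2-fold. Across the 9479 probes of that table, its log2 changes and those computed here had correlations of 0.993 to 0.999 over the 4 comparisons.

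Genes near P2rx7 were not called more often than others. Within 10 Mb, 130 of 267 genes (48.7%) were called after saline against 50.9% elsewhere (odds ratio 0.92, 95% interval 0.71 to 1.18, Fisher's exact p = 0.498), and 117 of 267 (43.8%) after LPS against 47.1% (0.88, 0.68 to 1.13, Fisher's exact p = 0.295).

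The interaction asked whether LPS acted differently in the 2 genotypes. The chemokine Ccl4 (4.86 ± 0.77, adjusted p = 0.0447) and Litaf, which encodes a factor induced by LPS (1.95 ± 0.28, adjusted p = 0.0301) responded more in knockout. The interferon-lambda receptor Ifnlr1 was also called (adjusted p = 0.0447), but it was not well above background on any knockout saline array, so its fitted difference is no bound, and normexp turned it to −0.70 (adjusted p = 0.322). Ccl4 changed by 0.08 in wild type and 4.93 in knockout, and Litaf by 0.03 and 1.98. Ccl3, not well above background on any knockout saline array (adjusted p = 0.101), Cxcl10 (6.57 ± 2.11, adjusted p = 0.455), Tlr2 (3.49, adjusted p = 0.282), Mx2 (2.15, adjusted p = 0.282), Cxcl16 (2.19, adjusted p = 0.23), Cebpb (1.95, adjusted p = 0.212) and Sox9 (1.03, adjusted p = 0.212) did not pass. In all, 7 genes were called, 5 up and 2 down, and 1343 had an unadjusted p under 0.05. No interferon-stimulated gene or NF-kB target was called over all genes with limma (20 of 36 and 7 of 22 when adjusted over the list alone), and 1 cytokine was (9 of 20). Their medians were 1.93, 1.48 and 3.16, with adjusted p = 0.267 each with an estimated correlation. Over the 600 genes called for LPS averaged over both genotypes, 423 rising and 177 falling, the slope of the knockout response on the wild-type response was 1.93. Medians were 0.80 in wild type and 2.16 in knockout for rising genes and −0.55 and −1.17 for falling genes. The shift of this set in the interaction had camera p = 7.23e-74 for rising genes (p = 0.0183 with an estimated correlation). This set was chosen by its LPS response on the same arrays, and these 2 p-values are not adjusted over lists. They thus describe the set and are no test on a list fixed beforehand. With slide as a block 16 genes were called, with normexp 0 (4092 at an unadjusted p under 0.05 with limma), where the median of all genes moved from −0.03 to −0.21. Without wild-type saline replicates 1 and 2, 1 gene was called, none of the 7, and the slope was 1.08. Ccl4 (4.25 ± 0.83, adjusted p = 0.167), Litaf (1.63, adjusted p = 0.0656) and Ifnlr1 (adjusted p = 0.161) did not pass there. Without all of slide 1 the slope was 1.05 and without slide 2 it was −0.91. No gene was called without wild-type saline replicate 1 or 2, knockout saline replicate 2, 3 or 4 or knockout LPS replicate 2 or 3 (1047 to 1394 at an unadjusted p under 0.05 with limma). The count was 1 without wild-type LPS replicate 1, 2 without wild-type saline replicate 3, 3 without knockout saline replicate 1 or knockout LPS replicate 4, and 11 without wild-type LPS replicate 2.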

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

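The tests on wild-type saline replicates 1 and 2, the fits without these arrays, and the regroupings of treatment and of values without the main effects were chosen only after the result was seen, and the other splits of the arrays were set before. The response to LPS differed between the genotypes for 7 genes in the interaction: for Ifnlr1 (1.46), AK144717 (3.73), Litaf (1.95), Ccl4 (4.86) and ENSMUST00000069631 (2.12) the fitted change with LPS was higher in knockout, and for Agxt2l1 (−2.25) and AK084144 (−1.37) it was lower. ENSMUST00000069631 changed by −1.63 in wild type and 0.49 in knockout, Agxt2l1 by 0.37 and −1.88 and AK084144 by 0.30 and −1.07. Ifnlr1 was not well above background on any knockout saline array and AK144717 only on knockout LPS arrays, so their values are no bounds, and normexp turned Ifnlr1 to −0.70 (adjusted p = 0.322). Of 100 drawn regroupings of genotype within treatment, 3 called at least 7 genes, the real one included, and the highest other counts of 8867 and 6855 nearly exchanged the genotypes between the treatments, which points to the genotype structure. Most regroupings mix the genotypes, whose averaged difference covered 12309 of 19463 genes, and so call few genes by construction, which leaves these splits without a bearing on chance. The same holds for 100 regroupings of treatment within genotype (3 with at least 7, the real one included), since 6 of the 7 genes were called for LPS in knockout; the highest other count there, 119, set slide 1 against slide 2 in wild type, and with slide as a block the real count was 16. After removal of both main effects, an approximate test, 1 of 100 regroupings of genotype within treatment, the real one, called 7 genes and the highest other split 1. The arrays spread unequally between genotypes, with an SD of the cytokine list of 2.5 in wild-type saline and 0.19 in knockout saline. These regroupings mix such arrays and ignore the slides, so they do not exclude chance for this count. Leaving out any 1 of 7 arrays ended all calls (limma, 1047 to 1394 genes at an unadjusted p under 0.05).

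In the interaction, 16 lists passed camera with the preset correlation and none with an estimated one (adjusted p = 0.267 to 0.623). Median interactions were 3.16 for cytokines and chemokines, 2.10 for activated endothelium, 1.96 for acute phase, 1.96 for reactive astrocyte markers, 1.93 for interferon-stimulated genes, 1.59 for neutrophil and monocyte markers and 1.48 for NF-kB targets. Smaller medians were those of striatum markers (0.68), the LPS receptor pathway (0.64, but −0.28 under normexp), the inflammasome list (0.60), glucocorticoid-responsive genes (0.42), immediate early genes (0.35), complement and antigen presentation (0.28), purinergic signalling (0.22) and the circadian clock (0.20). Oligodendrocyte precursor markers had a median of −0.57. Without wild-type saline replicates 1 and 2 the medians were 0.65 for interferon-stimulated genes, 0.78 for cytokines, 0.51 for NF-kB targets and −0.16 for acute phase. Leaving out 1 array ended the camera call of the complement, circadian, purinergic, immediate early or neutrophil and monocyte list for at least 1 choice of array (camera adjusted p up to 0.247).

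Genes that rose with LPS in knockout stood at LPS-like levels on wild-type saline replicates 1 and 2 (0.79 and 0.81 of the way from knockout saline to knockout LPS) and not on replicates 3 and 4 (−0.04 and −0.06). A swap of saline and LPS arrays within wild type would leave LPS arrays at the saline level, and the lowest lay at 0.52, which argues against it. A shift of the whole of slide 1 would move its LPS arrays too, but these differed from those of slide 2 by −0.25 while the saline arrays differed by 2.95. Genes that fell with LPS in knockout were lower on these saline arrays as well, by a median of −0.89, which is consistent with a wrong label or with LPS or inflammation in the mice behind these arrays. Tissue markers differed between the same arrays, with hippocampus markers at −1.09 and −0.88 on replicates 1 and 2 against 0.22 and 0.27 on replicates 3 and 4 (−1.07 to −0.84 on wild-type LPS arrays) and oligodendrocyte markers at 0.63 and 0.58 against 1.75 and 1.79, while hippocampus markers had a median of −0.14 for LPS in knockout with 0 of 9 called by limma, also over the list alone. A difference in the dissected tissue thus stays open beside these, the tables do not separate them, and no biological explanation within the design was tested.

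For LPS in wild type, 9 of the 35 splits of the 8 arrays called at least the 2 genes of the real split, so chance could not be excluded. The highest other count, 717, came from the split by slide, with 138 genes higher and 579 lower on slide 1 and 7 of them called for LPS in knockout. This points to a structure of the samples that follows the slide in part. Within slide 2, LPS called 245 genes, within slide 1 it called 2, and with slide as a block 3. The split that set wild-type saline replicates 1 and 2 with LPS replicates 2 and 3 called 518. It crosses the slides, since LPS replicate 2 lay on slide 2. On these arrays the genes rising with LPS in knockout lay at 0.79, 0.81, 0.88 and 0.83 of the way to knockout LPS, against at most 0.61 on the other wild-type arrays. Oligodendrocyte markers lay at 0.63, 0.58, 0.485 and 0.125, against 1.25 to 1.79. For LPS in knockout, 1 of 35 splits, the real one, called as many as 708 genes, and the highest other count was 4. Every other split there mixes saline and LPS arrays and so calls few genes by construction. These knockout splits are therefore without a bearing on chance.

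In 36 of 471 groups of 4 arrays, 1 array lay far from the other 3 (a gap beyond Dixon's 95% critical value), where chance gives about 1 in 20, or 23.6. Knockout saline replicate 1 was that array in 19 of the 36. This array also stood apart over the 9917 bright probes. It lay 0.855 to 0.881 (log2, scaled median absolute deviation of the difference) from the other knockout saline arrays, which lay 0.203 to 0.263 from each other. Its list levels were −1.84 for interferon-stimulated genes (others −2.19 to −2.17), 0.62 for immediate early genes (1.02 to 1.09), 3.81 for heat shock (3.34 to 3.40), 1.85 for the GABA system (2.51 to 2.64), −0.61 for cortex markers (0.10 to 0.17), 0.70 for basolateral amygdala markers (1.49 to 1.53) and −2.57 for the Y-linked list (−1.56 to −1.55). Its gene levels were −4.48 for Abcb1a, −6.53 for Cxcl1, −6.51 for Fam83d, −6.55 for Gprin3, −1.25 for Icam1, −1.60 for Mx2 and −1.21 for Nr1d2. They were 3.63 for Glo1, 3.72 for Mydgf, 4.29 for Nfkbia, 6.81 for Rpl19 and 2.90 for Slc22a6. Without this array, 756 genes were called for LPS in knockout and 19 for LPS in wild type.

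The other knockout saline arrays that stood apart were replicate 4 for oligodendrocyte markers (−0.03, others 0.17 to 0.20), replicate 3 for Cebpb (1.45) and replicate 2 for Lbp (−4.24). Among wild-type arrays, the heat shock list was low on saline replicate 2 (2.38, others 2.77 to 2.83) and on LPS replicate 1 (2.82, others 3.10 to 3.16). Striatum markers were high on LPS replicate 1 (1.11, others −0.19 to −0.04), glucocorticoid-responsive genes on LPS replicate 4 (2.74, others 2.49 to 2.53) and C1ra on LPS replicate 2 (−3.58). Among knockout LPS arrays, choroid plexus markers (−3.71, others −3.91 to −3.88), Litaf (3.11) and Mx2 (0.41) stood apart on replicate 1, and Mobp (1.15) and Zfp112 (−1.28) on replicate 3. Hypothalamus markers (−1.54, others −1.82 to −1.78), Nfkbie (−0.21), Nt5e (−0.21) and Per3 (−4.83) did so on replicate 4.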

How the results depend on the processing

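The fits without wild-type saline replicates 1 and 2, with the base composition correction and with calls that needed at least 2 probes, and the list tests without single arrays, were chosen only after the result was seen. Signal over background limits dim genes, for which only bounds are given. The cause of the moves below was not tested, except that the 2-fold minimum and the 2-probe rule are stricter by construction, and that the 2-probe rule tests 6330 genes. Within-slide fits and fits without a slide hold fewer arrays, but array number alone does not give their moves. For LPS in knockout, slide 3 alone called more genes than the fit without slide 4. Both hold the same knockout arrays, and the fit without slide 4 also pools the spread of the wild-type arrays into its error. The SD of the cytokine list was 2.5 in wild-type saline and 0.19 in knockout saline. The deposited processed list holds group means only, so its use as an alternative was not run, and a slope over the 2 genes called in wild type was not given. Over each comparison of named genes, 1153 of 1171 alternatives kept direction and side of the threshold for genotype after LPS (18 lost the call), 1195 of 1242 for genotype after saline (38 lost it, 9 turned direction), 1985 of 2198 for LPS in knockout (212 lost it, 1 turned), 515 of 550 for LPS in wild type (31 gained a call, 4 turned) and 264 of 336 for the interaction (64 lost it, 7 gained it, 1 turned).

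For genes changed by LPS in wild type (2), quantile normalization, the filter for all 16 arrays and the 2-fold minimum each called 1. Median centring, no filter, every probe, the variance trend, the fit without slide 3, the base composition correction and the 2-probe rule each called 0 with limma (736 to 1715 genes at an unadjusted p under 0.05). The 2 groups alone gave 7, slide as a fixed block 3, as a random block 4, slide 2 alone 245, and fits without slide 1, 2 or 4 gave 413, 90 and 10. Without saline replicates 1 and 2 there were 611, and without each array in turn 0 to 19.

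For genes changed by LPS in knockout (708), normexp called 429, slide 4 alone 178, the fit without slide 3 1, the fit without slide 4 0 (limma, 2193 at an unadjusted p under 0.05) and the 2-probe rule 92. Without each array in turn there were 430 to 756, and all other settings gave 498 to 978.

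For genes changed by genotype under saline (9907), the 2-fold minimum left 5774, the 2-probe rule called 1462 (1266 shared with the calls here) and without each array in turn there were 8549 to 9931. For genes changed by genotype under LPS (9178), these were 5199, 1254 (1054 shared) and 7916 to 10840. The base composition correction called 8574 and 7981, of which 6534 and 6079 were shared.

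For genes with a genotype by LPS interaction (7), normexp, the fits without slide 3 or slide 4 and the 2-probe rule called 0 with limma (693 to 4092 at an unadjusted p under 0.05). Quantile normalization called 11, median centring 3, no filter 1, the filter for all 16 arrays 1, every probe 2, the variance trend 2, slide as a fixed block 16 and as a random block 17. The fit without slide 1 called 3, without slide 2 584 (412 up, 172 down), without wild-type saline replicates 1 and 2 it called 1, the base composition correction called 2, and without each array in turn there were 0 to 11. The slope of the LPS response (1.93) was 2.32 over genes called in knockout, 1.08 without wild-type saline replicates 1 and 2, 1.05 without slide 1 and −0.91, a reversed sign, without slide 2.

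With an estimated correlation, 0 lists passed camera in each of the 5 comparisons, against 17 for LPS in wild type, 17 for LPS in knockout, 9 and 3 for genotype after saline and LPS and 16 for the interaction. With the base composition correction 7 passed for genotype after LPS, and without wild-type saline replicates 1 and 2, 7 passed for the interaction. Slide as a block left 16, 16, 8, 3 and 18.

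The change of P2rx7 lay between −1.70 and −1.35 after saline and between −1.74 and −1.52 after LPS without each array in turn, and the other probe gave 0.24 and 0.063. It was −0.81 and −1.0 with the base composition correction, −1.94 and −1.84 without slide 1 and −1.08 and −1.46 without slide 2. Under normexp, the saline genotype difference turned to 0.88 for Fam83d, 0.017 for Gbp4, 0.10 for Gprin3, 0.72 for Il6, 0.055 for Isl1, 0.21 for Npas2, 0.27 for Per3 and 0.08 for Supt7l, and the interaction of Ifnlr1 to −0.70. With the filter for all 16 arrays, which takes another probe, Ptx3 turned to 0.40 for saline genotype and −0.28 for LPS in knockout. Within slide 1, and without slide 2, the LPS response in wild type was −0.61 for Cxcl10 and −0.55 for Cxcl9. Windows of 5 and 20 Mb around P2rx7 gave odds ratios of 0.94 and 0.98 after saline and 0.92 and 0.85 after LPS.

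With the replicate number as a block, 0 genes were called for LPS in wild type and 0 for the interaction (limma, 1151 and 1214 at an unadjusted p under 0.05), 576 for LPS in knockout, 9339 for genotype after saline and 8579 after LPS. Arrays of the same number in different groups had correlations of −0.381 to 0.337 between their deviations from the group means (median −0.015). Of these pairs 2 of 24 were above 0.1, against 13 of 72 pairs of different numbers. No pairing by number was thus detected, although a weak one is not excluded.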

Other observations

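In this part, the tests of disagreement between probes and of the span of choroid plexus markers within a slide were chosen only after the result was seen, as were the correction for base composition and the list tests without single arrays. In knockout mice, LPS lowered 2 of 11 markers of the meninges and fibroblasts, the organic anion transporter Slc22a6 (−2.15 ± 0.40, log2, SE, n = 4 per group, adjusted p = 0.00637) and the collagen gene Col1a2 (−1.06 ± 0.22, adjusted p = 0.0118, 0.0584 under normexp). When adjusted over the list alone 7 fell and 2 rose, and the list did not pass (median −0.82, camera adjusted p = 0.0672, but 0.0237 without knockout LPS replicate 4). Within slides 3 and 4, Slc22a6 changed by −2.0 and −2.29 and the list by −0.78 and −0.68. None of 6 blood markers was called over all genes with limma, and 4 fell when adjusted over the list alone (median −0.67, camera adjusted p = 0.0461, adjusted p = 0.147 with an estimated correlation), a camera call lost without knockout saline replicate 1 or 2 or knockout LPS replicate 2 or 4 (0.0551 to 0.111). Among 12 astrocyte markers, 2 rose (2 up and 1 down over the list alone, camera adjusted p = 0.264), of which the transcription factor Sox9 rose by 1.09 ± 0.17 (adjusted p = 0.00225). Oxidative phosphorylation genes had a median of −0.28 after LPS in knockout with none of 86 called by limma, also over the list alone (camera adjusted p = 5.93e-06, adjusted p = 0.439 with an estimated correlation), and −0.03 under normexp. Without knockout saline replicate 1 their median was −0.182 (camera adjusted p = 0.00225) and 1 of 86 fell. In the circadian clock list 1 of 16 rose (1 over the list alone; median 0.24, −0.02 under normexp; camera adjusted p = 0.00974, adjusted p = 0.111 with an estimated correlation).

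Between the genotypes after saline, transmitter genes were called in both directions. Of 19 genes of the GABA system 4 were higher and 9 lower in knockout (the same over the list alone, camera adjusted p = 0.353), and of 26 of the glutamate system 10 were higher and 4 lower (12 and 4 over the list alone, camera adjusted p = 0.364). Of 10 hypothalamus markers 5 were higher and 1 lower (the same over the list alone, median 0.69, camera adjusted p = 0.292), of 10 cortex markers 5 were lower (5 over the list alone, median −0.68, camera adjusted p = 0.179), and of 10 thalamus markers 4 were lower and 1 higher (the same over the list alone, median −0.47, camera adjusted p = 0.194). Of 4 measured Y-linked genes, 2 were lower in knockout after saline (median −0.64, camera adjusted p = 0.194) and 3 after LPS (median −0.93, camera adjusted p = 0.178), with the same numbers over the list alone. Knockout saline replicate 1 stood apart on several of these lists. Without it the mean genotype difference after saline moved from −0.53 to −0.28 for the Y-linked genes (1 higher and 2 lower) and from −0.24 to −0.06 for the GABA system (6 higher and 7 lower). The median moved from −0.64 to −0.49 for the Y-linked genes and from −0.68 to −0.35 for cortex markers (2 higher and 4 lower). By the level per array, the exact permutation p took its smallest possible value of 0.0286 for 1 of 40 lists for LPS in wild type, 20 for LPS in knockout, 18 for genotype after saline and 23 for genotype after LPS.

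Genotype calls covered about 1 gene in 2 (9907 after saline and 9178 after LPS), and the scan sessions followed the genotypes. In each case 1 of 35 splits, the real one, gave as many genes (highest other 1 and 3). Every other split mixes arrays of both scan sessions and so calls few genes by construction, which leaves these splits without a bearing on chance. Changed transcript levels as the whole cause would move the probes of a gene alike, and 38.7% of genes with at least 2 called probes had probes going opposite ways. Base composition of the probes as the whole cause would end the calls once corrected, and 65.4% were kept. Unequal labelling along the transcript as the whole cause was set to be excluded by a median difference between 5′ and 3′ probes near 0, and this was −0.06 over 4365 genes, but the genes went both ways (48.0% higher at the 5′ probe, median size 0.82), so that bound was wrong and the explanation stays open. A mixture of genotype, scan session and labelling may lie behind these calls, and the design cannot tell genotype and session apart.

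Choroid plexus markers differed between wild-type arrays, with list levels of −3.85, −3.75, −1.83 and −1.57 on saline replicates 1 to 4 and −1.08, −2.22, −1.59 and −4.28 on LPS replicates 1 to 4, and lay between −4.66 and −3.60 on knockout arrays. Choroid plexus tissue in some of the dissected samples would make the markers rise and fall together, and the median correlation between pairs of markers over the 8 wild-type arrays was 0.90, against 0.21 at the 95th percentile of random lists. Ttr, the main secreted protein of the choroid plexus, lay between −6.34 and −0.02 on wild-type arrays, while 8 of the 12 markers, none of which is in another list, were also well above background on all 4 knockout LPS arrays. A shift of a whole slide would keep the arrays of a slide together, and on slide 1 they spanned 2.78. Tissue carried over in dissection, with no sort or gate named in the labels, is a candidate explanation for this spread, and a biological cause was not tested.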
